A study of Mus musculus with 16 samples.

How the data were processed

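Chromatin accessibility was measured by ATAC-seq in peritoneal B-1a cells of mice, and 1 peak list for each of 6 Bcl11a knockout libraries was used. Of the 16 samples in the series, 10 were not analysed here. Per the labels' protocols, nuclei were cut with Tn5 and paired-end sequencing was usually done on an Illumina NovaSeq instrument. The submitters' processing notes name the mm10 build and Trim Galore 0.6.7, BWA 0.7.17, Picard 3.0.0, SAMtools 1.15.1, MACS2 2.2.7.1, deepTools 3.5.1, ChIPseeker 1.38.0, HOMER 4.11 and DiffBind 3.12.0, with no role or order. Filters, the shift of reads for the Tn5 cut and the peak calling options are not given in the sources used here. Each deposited list belongs to a single library, so peaks were called per library and libraries served as replicates.

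The deposited lists give, for each peak, a fold enrichment at the summit over the local background, which is a ratio within that library, the −log10 p and −log10 q of the summit, and a display score. These are the authors' values. They were used to rank and filter peaks, to set deciles of peak strength, and to recover pileups and backgrounds as described next. The lowest −log10 q in the lists corresponds to a q threshold of 0.05. The files held no peak outside chromosomes 1 to 19, X and Y. Fold and −log10 p together were solved for a whole-number summit pileup and a background, taking fold as pileup plus 1 over background plus 1 and p as the Poisson probability of a higher pileup. Within a relative tolerance of 0.001 this held for 99.63% and 99.62% of the young female peaks and 100% of the others. The lowest background per library served as the measure of depth, since no read totals were used here.

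Peaks of the 6 libraries were merged where they overlapped by 1 bp, giving 43207 regions. A region or gene counted as only in a group where both of its libraries had a peak and neither library of the other group did. Gene coordinates came from a RefSeq gene table of GRCm38.p6, the same build as mm10. It gives gene extents without strand or exons, so a peak within 1 kb of either end of a protein-coding gene stood in for a promoter peak, a departure from the planned distance to transcription start sites. Some of these peaks therefore lie at the 3′ end of a gene. As a check of the build, 32.7% to 49.3% of peaks lay at gene ends, against 6.62% to 8.34% with all genes shifted by 100000 bp. Of 391 listed genes 390 matched the 21887 protein-coding genes, 2 of them by a synonym. The planned motif analysis was not run because it needs genome sequence.

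Peak numbers were compared by exact permutation of log2 values, and library similarity by the exact permutation of 6 libraries into 3 pairs. For 20 gene lists fixed before the data were examined, the number of genes kept from the deeper group (young females, or old males) in both old female libraries was compared with 10000 random lists matched on decile of peak strength, with Benjamini-Hochberg adjustment. The lists were B cell identity, B-1a cell, follicular and marginal zone B cell, plasma cell and secretion, B cell receptor signalling, Toll-like receptor and NF-kB signalling, age-associated B cell and senescence, survival and apoptosis, cell cycle, partners of Bcl11a, ribosomal proteins and translation, housekeeping, mitochondrial metabolism, T cell, macrophage, mast cell with eosinophil and neutrophil, natural killer and dendritic cell, mesothelial and stromal, Y-linked, and X-linked genes with a Y homologue. The naming rule, also fixed before, took Bcl11a, up to 12 genes per comparison and direction ranked by the lower −log10 q of the 2 libraries, up to 3 regions away from gene ends, and 2 to 4 members of each list in order of strength among those kept and among those not. Predicted, olfactory and receptor segment genes were not named.

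Alternatives were a −log10 q of 5 or more, the 4850 strongest peaks of every library, peaks covering 50% of a region, a peak in either library, 2.5 kb around gene ends, peaks in the gene or within 5 kb of it, matching on fold enrichment, a replicate block, leaving out each library, and matched depth. For matched depth, pileups were thinned binomially to the lowest background and peaks with a Poisson −log10 p of at least 4.27, the lowest in the shallowest list, were kept, in 20 draws. Thinning can only drop listed peaks, so it adds no weak peaks of the kind a shallow library holds. Chosen after the data were seen were the rule that the summit lie within 1 kb of a gene end, matched depth for peak numbers, gene lists, gene-end shares and X peaks, the odds ratios (Mantel-Haenszel, over deciles of strength in 1 library) of calls at gene ends in the other replicate and in the old females, and the check for old female peaks under the young peaks of list members. Thinned shares per decile are means over the first 5 draws, and matched depth for lists, gene-end shares and X peaks used the first draw.

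On simulated data for the age comparison with 6000 regions and no loss, the full lists gave 3067 regions only in the deeper group, and matched depth gave 132 against 148 in the other direction. With 200 strong regions removed, 68.5% of them were recovered as lost at matched depth. The simulated libraries shared the positions of 1 young library and differed by counting error alone, apart from depth and the removed regions. Random lists of 20 genes passed an unadjusted 0.05 in 1% of 400 trials for age (10828 genes) and 1.75% for sex (3343 genes). Lists of 20 genes kept 50 percentage points more often than matched genes passed the adjusted threshold in 98.3% of 60 trials for age and 81.7% for sex. At 25 points the shares were 36.7% and 16.7%, and for lists of 5 genes at 50 points 26.7% and 0%. Lists kept less often than matched genes were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.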

Results

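ATAC-seq, which reads open chromatin from the DNA that the Tn5 transposase can cut, was compared across 6 libraries from Bcl11a knockout mice. The cells were peritoneal B-1a cells, the innate-like B cells of the body cavities. Bcl11a encodes a zinc finger transcription factor needed for B cell development. The libraries fell into 3 groups of 2 replicates: young female, old female and old male knockouts. Wild-type mice were aged 3 months (young) or 24 months (old) in the design text, while the labels of these 6 libraries say only young or old. The 8 wild-type samples and the 2 young male knockout samples of the series were not analysed here, so no value below measures the effect of the deletion itself. The series asks how the maintenance of B-1a cells during aging depends on Bcl11a, and the files allow a comparison of age within knockout females and of sex within old knockouts. Nothing in the labels says whether replicates came from separate mice, so n counts libraries.

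The young female libraries held 30783 and 32500 peaks, the old female libraries 5950 and 4850, and the old male libraries 8722 and 10112. Peaks covered 24.9 and 26.5 Mb in the young females, 2.52 and 2.03 Mb in the old females, and 3.99 and 4.42 Mb in the old males. Peak lists give no read totals, but the background behind each peak could be recovered, and its lowest value in a library tracks depth. That value was 1.34 and 1.13 reads in the young females, 0.0538 and 0.0525 in the old females, and 0.0613 and 0.0676 in the old males. By this measure the young female libraries were 25.6 and 21.5 times as deep as the shallowest library, and the old male libraries 1.17 and 1.29 times. The median summit stood on 43 and 41 reads in the young females, 6 and 6 in the old females, and 7 and 7 in the old males. Depth therefore followed age in the female comparison, and most of the weaker young regions would not be called at the lowest depth.

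**Figure D1:**
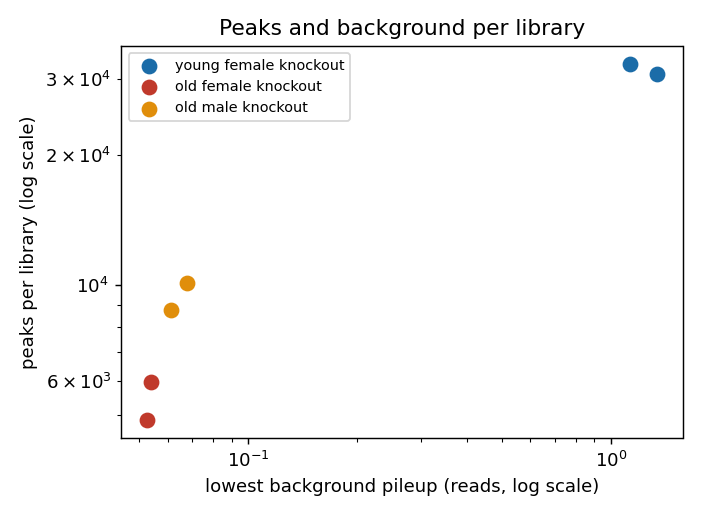
Peaks per library against the lowest background pileup of that library, in reads, both on log scales, with 1 point per library coloured by group. The young females lie at 1.13 and 1.34 reads with 32500 and 30783 peaks, and the 4 old libraries lie at 0.0525 to 0.0676 reads with 4850 to 10112 peaks.

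At Bcl11a itself (chromosome 11, 24076564 to 24173558, mm10), each young female library had 10 peak regions within the gene or 1 kb of its ends. The strongest lay inside the gene at 24141078 to 24142525, with −log10 q of 83.5 and 88, and the next at 24077137 to 24078082, close to the gene's lower-coordinate end, with 69.2 and 69.7. Neither old female library had a peak there, nor did old male replicate 1. Old male replicate 2 had 1 peak in the strongest region, with −log10 q of 2.07 on 5 reads. At the lowest depth the strongest region would have been called with a probability of 0.605 and 0.663 if openness had been as in the young, and the region at the lower end with 0.574 and 0.605. The labels do not say which part of the gene was deleted, so these peaks check nothing about the knockout.

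**Figure D2:**
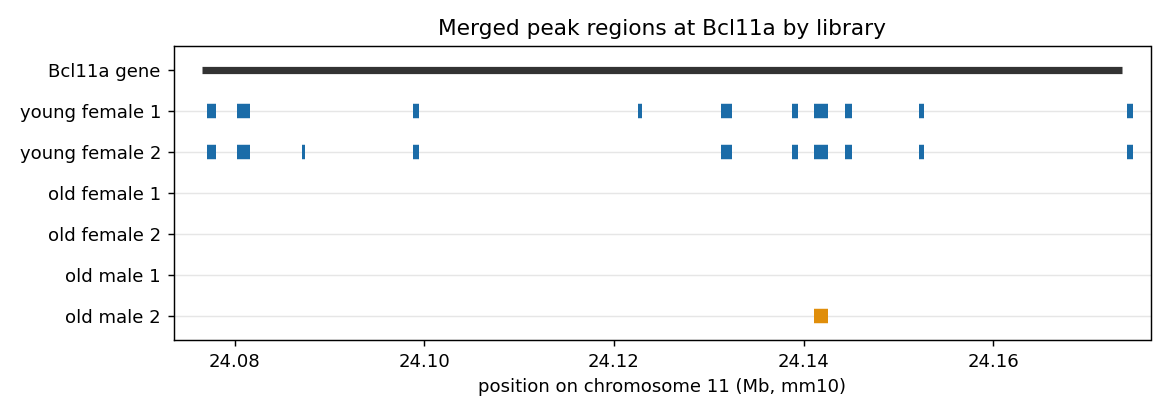
Merged peak regions along Bcl11a on chromosome 11 (x axis, position in Mb, mm10), with 1 row per library and the gene's extent on top; a block marks a region in which that library had a peak. Young female libraries have 10 blocks each, old male replicate 2 has 1, and the other 3 libraries have 0.

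Age was compared first, in knockout females. Nearly all regions open in both old female libraries were also open in both young ones: 2149 of 2157 regions (99.63%), and 2004 of 2005 genes by peaks at their ends. In the other direction 22568 regions and 6613 genes had peaks in both young libraries and in neither old one. No gene had peaks in both old libraries and in neither young one. The shared part of the old female regions leaned on the deeper young lists. With all libraries thinned to the lowest depth it was 79.83% (1714 of 2147, medians over draws). Counting a peak in either library it was 61.47% of 8622 old female regions. That setting left the young depth unchanged and let in peaks of a single old female library, so it does not bear on young depth. Genes kept in all 4 libraries included Pou2af1, a B cell coactivator, Hspa5 and Hsp90b1, chaperones of the secretory pathway, Relb, an NF-kB subunit, Klf2, a regulator of B cell trafficking, and Pcna, the DNA polymerase clamp. Among genes without a peak at their ends in either old female library were Ebf1, a B lineage transcription factor, Il10, the cytokine that B-1 cells secrete, and Atm, a DNA damage kinase. At the lowest depth, the young peaks of Ebf1 would have been called with a probability of 0.71 and 0.736, those of Il10 with 0.565 and 0.757, and those of Atm with 0.963 and 0.984. Both old male libraries had peaks at the ends of Ebf1 and Atm, and neither had one at Il10.

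Mean peak number was 31642 ± 1214 (SD, n = 2) in young and 5400 ± 778 (SD, n = 2) in old females, 5.89-fold apart by the difference of log2 means. The exact permutation test (two-sided) gave p = 0.333, the smallest that 2 libraries against 2 allow. With all libraries thinned to the lowest depth, a comparison of peak numbers chosen after the data were seen, the means were 9806 ± 1417 and 5314 ± 656 (SD, n = 2), 1.84-fold apart. Thinning drops young peaks and adds none. The full old female lists held 1318 and 1250 peaks of 3 reads or fewer, of which 1.67% and 2.32% overlapped a peak of the other replicate. The 1.84-fold is therefore not the difference between libraries sequenced to equal depth. At that depth, regions found only in the young fell to 2528 (2454 to 2595 over 20 draws) and those only in the old numbered 73 (56 to 83). With the 4850 strongest peaks of every library the counts were 1176 and 129. Without old female replicate 1 the count only in the old was 1553 regions, and without old female replicate 2 it was 1775, against 6 with both; a peak in the 1 library left then suffices, which raises the count by construction.

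Among the regions of both young libraries, the strongest decile was called in both old female libraries for 58.3% and in neither for 14.6%. The ninth decile was called in both for 14.1%, and the fifth for 0.395%. Thinned to the lowest depth, 86.4%, 54.7% and 3.44% of these deciles would still have been called in both young libraries.

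**Figure D3:**
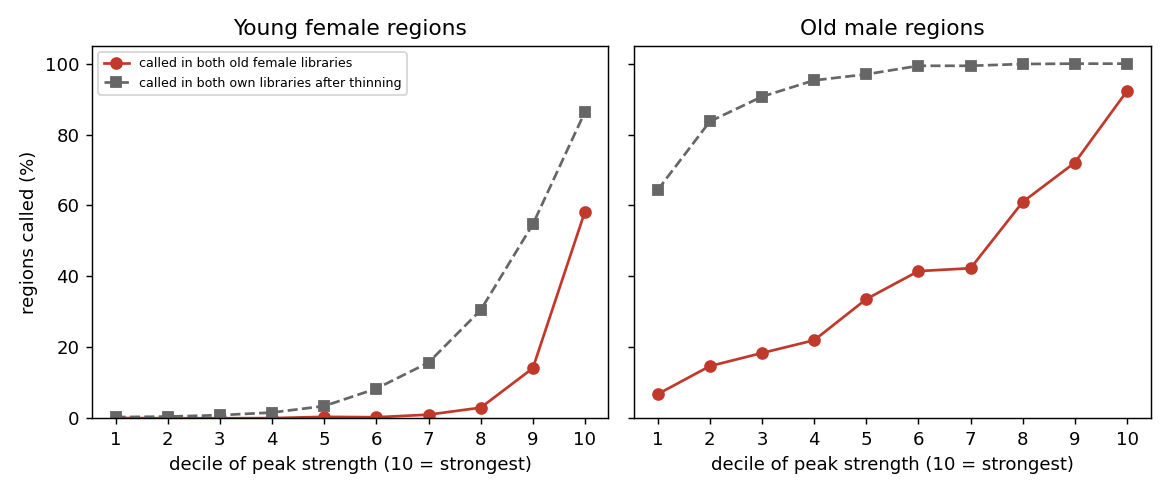
Share of regions called (y axis, %) by decile of peak strength (x axis, mean −log10 q, 10 strongest), for regions of both young female libraries on the left and of both old male libraries on the right. Circles give the share called in both old female libraries and squares the mean share, over 5 draws, called in both libraries of the starting group after thinning to the lowest depth; in the strongest decile these are 58.3% and 86.4% on the left, and 92.3% and 100% on the right.

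The 12 genes that the naming rule put first among those with peaks only in the young were Clec11a, Septin4, Gtpbp2, Nlk, Rgs17, Mrpl18, Tjp3, Pxmp4, Kat6b, Erbb3, Arih1 and Pkd1, with −log10 q of 210 to 366. For 10 of these 12 the old female libraries did have a peak under the same young peak, outside the 1 kb window that the young peak reached. For these 10 the difference thus lay in the extent or place of the peaks at the window and not in the presence of a peak. Of the 12, only Nlk and Pxmp4 had no old female peak there. Nlk, a serine/threonine kinase of the Wnt pathway, had a peak at 78697367 to 78698138 on chromosome 11 with −log10 q of 355 and 267. Pxmp4, a peroxisomal membrane protein gene, had 250 and 241 at 154603469 to 154604454 on chromosome 2. Counting only genes whose summit lay within 1 kb of an end, a rule chosen after the data were seen, left 6170 genes only in the young, of which 6146 had no old female peak over either young peak. The strongest of these after Nlk and Pxmp4 were Srd5a3, Pkd2l1, Hexim1, an inhibitor of transcription elongation, and Pgk1, a glycolytic kinase. Srd5a3 had −log10 q of 202 and 225, Pkd2l1 225 and 201, Hexim1 197 and 208, and Pgk1 196 and 215. Atm and Npat, which share a divergent promoter at 53536441 to 53537441 on chromosome 9, had 189 and 204. At the lowest depth the peaks of these genes would have been called with a probability of at least 0.948 in each young library. Old male libraries did have peaks over these young ones, 1 library at Nlk and both at Pxmp4, Srd5a3, Pkd2l1, Hexim1, Pgk1, Atm and Npat. The absence at these genes was therefore not common to the old libraries.

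Away from gene ends, strong regions only in the young were on chromosome 17 at 31753195 to 31754191, 71465 bp from Cryaa, with −log10 q of 260 and 281, and within Inpp5d, the gene of the SHIP-1 phosphatase, at 87650257 to 87651641 on chromosome 1 (286 and 253). Both had peaks in both old male libraries. The strongest of the 6 regions only in the old lay at 195017996 to 195018559 on chromosome 1, 20412 bp from Cd46, with 8.71 and 10.2. The second was within Lingo2 at 36611500 to 36611858 on chromosome 4 (5.63 and 5.44), and the third 46003 bp from Fggy at 95511125 to 95511477 on chromosome 4 (1.89 and 2.45).

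Of 27 B cell identity genes, 25 had a peak at their ends in both young libraries and 6 of those in all 4, against 4.84 in random lists matched on peak strength. Pou2af1 had −log10 q of 281 and 262 in the young and 15.5 and 14.7 in the old, and Ms4a1, which encodes CD20, 213 and 233, and 5.32 and 5.97. Bach2 was called in old female replicate 1 and Cd72 in replicate 2, and Ebf1 (101 and 95.9) in neither. Of the 19 B-1a genes with peaks in both young libraries 0 were kept in all 4, against 0.976 in matched lists, and 14 had no peak in either old female library. Zbtb32, with 123 and 127 in the young, Bhlhe41, a regulator of B-1a cells, with 97.8 and 103, and Cd9 with 124 and 91.9 were called in 1 old female library each, while Plscr1, with 88.9 and 82.7, was called in neither. The follicular and marginal zone list kept 1 of 11 (1.11 expected), which was Klf2 (207 and 215 in the young, 22.5 and 18.4 in the old); S1pr1 and Il4ra were not called in the old females. Plasma cell and secretion genes kept 4 of 14 (4.57 expected), namely Hsp90b1, Ell2, Dnajb9 and Hspa5, while Sec61a1 and Irf4 were called in neither old female library.

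Genes of B cell receptor signalling kept 4 of 23 (4.63 expected), led by Malt1 and Bcl10, partners in NF-kB activation, with 235 and 250, and 214 and 227, in the young. Lyn and Syk, kinases next to the receptor, were called in old female replicate 1 and not in replicate 2. Toll-like receptor and NF-kB genes kept 7 of 25 (5.61 expected), with Relb at 281 and 276 in the young and 40.8 and 26.1 in the old. Tnfaip3 was called in 1 old female library and Ticam1 in neither. The list of age-associated B cell and senescence genes kept 2 of 13 (3.05 expected), the cell cycle inhibitors Cdkn1b and Cdkn2d, and lacked Atm. Survival and apoptosis genes kept 5 of 21 (3.87 expected), among them Birc3 and Casp9, while Bcl2l11 and Bid had no old female peak. Cell cycle genes kept 5 of 26 (5.11 expected), led by Pcna and Mcm4, and Mcm7 and Mcm5 were not called. NuRD, BAF and corepressor partners of Bcl11a kept 6 of 21 (5.16 expected), led by Gatad2a, Mbd3 and Gatad2b.

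Ribosomal and translation genes kept 8 of 19 (5.21 expected), led by Rps19 and Ncl, while Npm1 and Rpl4 were not called in the old females. Housekeeping genes kept 5 of 15 (3.27 expected), with B2m and Tfrc kept and Pgk1 not called; Aldoa had no peak at its ends in the old females, but both had a peak under the wider young one. Mitochondrial genes kept 3 of 20 (3.23 expected), with Atp5b and Sod2 kept and Atp5a1 and Ndufv1 not called. Among markers of other cells, 6 of 19 T cell genes and 9 of 18 macrophage genes had peaks at their ends in both young libraries, against 10828 of all 21887 genes. T cell genes kept 2 of 6 (0.757 expected), which were Cd2 and Cd3d, macrophage genes 0 of 9 (0.149), mast cell, eosinophil and neutrophil genes 0 of 1 (0.0033), natural killer and dendritic cell genes 0 of 4 (0.279), and mesothelial and stromal genes 0 of 4 (0.0045). Y-linked genes had no peak in the females. X-linked genes with a Y homologue kept 4 of 5 (1.33 expected), namely Kdm5c, Eif2s3x, Ddx3x and Usp9x, with Kdm6a not called. That list had the lowest value of the 19 tested, p = 0.025 in the permutation of matched random lists and 0.47 after Benjamini-Hochberg adjustment, and the other lists had an adjusted p of 1. The expected counts depended on the matching: with genes matched on fold enrichment they were 1.79 for B cell identity, 1.81 for plasma cell and secretion, 2.1 for B cell receptor signalling, 2.11 for survival and apoptosis, 1.63 for age-associated B cell and senescence and 0.44 for T cell genes, all lower than by strength. They were higher for B-1a cell (1.56), macrophage (0.669), natural killer and dendritic cell (0.583), mast cell, eosinophil and neutrophil (0.0333) and mesothelial and stromal genes (0.266). In that setting permutation p was 0.012 for B cell identity, 0.014 for X-linked genes with a Y homologue and 0.04 for ribosomal and translation genes, or 0.13, 0.13 and 0.25 after adjustment. Over the settings run, adjusted p ranged from 0.13 to 1 for B cell identity, from 0.061 to 1 for the X-linked genes and from 0.25 to 1 for ribosomal genes. Of the 157 list members with peaks at their ends only in the young, 155 had no old female peak over their strongest young peaks, a check chosen after the data were seen. Of the 19 lists, matched on peak strength, 0 passed an adjusted 0.05 and 1 an unadjusted 0.05, and these p-values describe genes in these libraries, not groups of mice. Where few genes were expected to be kept, the test could not find excess loss. For B-1a genes 0 kept, the lowest count possible, gave p = 0.71 in the permutation of matched random lists. For such lists the result does not speak to loss.

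Sex was compared next, in old knockouts, where depth differed little. The old males had peaks in both libraries at 1405 regions and 723 genes without a peak in either old female, and the old females at 95 regions and 59 genes without one in either old male. Genes with peaks at their ends only in the old males included Ect2, a regulator of cytokinesis, the early response genes Ier2 and Atf3, the DNA repair genes Atm and Ercc4, and Pgk1. Genes with peaks only in the old females included Tada2b, a subunit of histone acetyltransferase complexes, Abcf1, Ltn1, a ribosome quality control ligase, and Maml1, a Notch coactivator. All 24 genes named by rank had peaks in both young female libraries, so the 12 only in old males were not male-only across the 6 libraries. The 12 only in old females had peaks in all 4 female libraries and in neither male one. The deeper young females had peaks at 2004 of the 2005 genes open in both old females. Their peaks at these 12 were thus all but given and do not mark a female trait.

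Mean peak number was 9417 ± 983 (SD, n = 2) in old males and 5400 ± 778 (SD, n = 2) in old females, 1.75-fold apart, with p = 0.333 in the exact permutation test (two-sided), the smallest possible. At matched depth the counts of regions were 1214 only in males and 108 only in females, and with equal list lengths 679 and 172. Leaving out a library raises both counts by construction. In its own group 1 peak then suffices, and for the other group only 1 library must lack a peak. Without old female replicate 2 the region counts were 1841 only in males and 2435 only in females, and without old female replicate 1 2188 and 1981. Without old male replicate 1 they were 6226 and 187, and without old male replicate 2 5221 and 282. With a peak in either library of each group they were 10042 and 4321.

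The strongest male-only gene, H2-DMb2, which acts in antigen presentation, had −log10 q of 27.1 and 24.3, but an old female peak lay under its peak outside the 1 kb window. The other 11 had no female peak there. Ect2 had 22.9 and 22.1 at 27153809 to 27154149 on chromosome 3, Ier2 23 and 21.6 at 84661283 to 84661978 on chromosome 8, and Selenok, a selenoprotein gene, 21 and 22.8. Atm and Npat had 20.2 and 21.5 at their shared promoter on chromosome 9, Pgk1 19.6 and 30.6 on the X, Ercc4 18.8 and 21.4, Endod1 17.7 and 17, Pkd2l1 20.7 and 16.5, Atf3 15.7 and 15.9, and Mphosph8 14.6 and 15.8. The 12 female-only genes had weaker peaks, of 4.76 to 14.3. Pwwp3a had 12.8 and 8.59 at 80226425 to 80226877 on chromosome 10, and Ccdc96 and Tada2b, which share a peak at 36484253 to 36484520 on chromosome 5, 6.75 and 14.3. Slco5a1 had 11.9 and 6.46, Abcf1 10.1 and 6.21, Ltn1 5.81 and 5.61, and Ergic3, Plekhm1, Dnajc7, Maml1, Eci1 and Stk17b completed the list. Away from gene ends, males alone had regions within Tnfrsf8, which encodes CD30, at 145299965 to 145300759 on chromosome 4 (26.5 and 34.8), 52917 bp from Chd2 at 73594663 to 73596061 on chromosome 7 (26.1 and 31.7), and the Inpp5d region named above (22 and 35). Females alone had regions 11382 bp from Vps52 on chromosome 17 at 33978420 to 33979387 (13.3 and 12.7), at the Cd46 region named above, and 12769 bp from Prrc2b on chromosome 2 at 32137507 to 32138262 (6.75 and 11.3).

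By gene list, the old females kept 6 of the 8 B cell identity genes open in both old male libraries (5.49 expected). Ebf1 was the gene of that list open only in males, with −log10 q of 4.72 and 3.82. The old females kept 0 of 6 B-1a genes (1.93 expected), with Zbtb32, Bhlhe41 and Cd9 called in 1 old female library each. Il5ra (5.67 and 8.51), Plscr1 (5.19 and 5.26) and Siglecg (3.53 and 6.04) were open only in males. Here only in males refers to the old libraries, since both young females had peaks at Ebf1, Il5ra, Plscr1 and Siglecg. Follicular and marginal zone genes kept 1 of 3 (1.57 expected), plasma cell and secretion genes 4 of 7 (5.39), with Sec61a1 and Mzb1 open only in males, and B cell receptor genes 4 of 8 (4.06). Toll-like receptor and NF-kB genes kept 7 of 10 (5.28), with Irak4 only in males, age-associated and senescence genes 2 of 4 (2.52), survival genes 5 of 7 (3.57), cell cycle genes 5 of 8 (3.84), with Mcm7 only in males, and partners of Bcl11a 5 of 9 (5.14). Ribosomal and translation genes kept 8 of 11 (5.12), housekeeping genes 3 of 8 (3.57), mitochondrial genes 2 of 5 (1.75), T cell genes 2 of 2 (1.22) and natural killer and dendritic cell genes 0 of 1 (0.249). X-linked genes with a Y homologue kept 3 of 3 (0.784 expected), and Kdm5c had peaks in both old females and neither old male. Macrophage, mast cell, mesothelial and Y-linked lists had 0 genes open in both old male libraries. The lowest p over the 16 lists tested in the permutation was 0.033, for the X-linked list, and 0.41 after Benjamini-Hochberg adjustment. Of the lists, 0 passed an adjusted 0.05 and 1 an unadjusted 0.05. As for age, lists with few expected genes could not show excess loss: 0 of 6 B-1a genes gave p = 0.2 in the permutation.

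Across all 6 libraries, 1783 of the 43207 merged regions had a peak in every library, and 17356 had peaks in both young females and in none of the 4 old libraries. Regions in both young females and both old males but in neither old female numbered 1385, among them those at Atm and Npat, Pgk1 and Inpp5d, and those in both young and both old females but in neither old male 89. No region had peaks in both old females and both old males without a young female peak. With the 4850 strongest peaks of each library, base-pair Jaccard indices were 0.760 for the young female pair, 0.410 for the old male pair and 0.249 for the old female pair. Both old female libraries overlapped more with the old males (0.302 and 0.312 for replicate 1, 0.255 and 0.263 for replicate 2) than with each other, but with full lists the order turned (0.226 for the pair, 0.218 and 0.223 for replicate 1, 0.195 and 0.194 for replicate 2). The mean within groups exceeded that between groups by 0.211, the highest of the 15 ways to pair the libraries (exact permutation test, one-sided, p = 0.0667, the smallest possible).

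Peaks within 1 kb of a gene end made up 33.6% (95% exact interval 33 to 34.1) and 32.7% (32.2 to 33.2) of the young female lists, 49.3% (48 to 50.6) and 47.9% (46.5 to 49.3) of the old female lists, and 42.3% (41.3 to 43.4) and 43.3% (42.3 to 44.2) of the old male lists. These intervals cover counting error only. The direction turned with list length: with the 4850 strongest peaks each, the difference was -18.4 percentage points for old minus young females and -7.33 for old females minus old males. At matched depth the same differences were -3.77 and 3.11 percentage points. At −log10 q of 5 or more they were 39.8 and 12.8. The full old female lists held 1318 and 1250 peaks of 3 reads or fewer, and the young female lists 0. Thinning adds no such peaks to the young lists, so for age neither equalised setting compares lists of like make-up. X-chromosome peaks numbered 22.5 and 22.6 per 1000 autosomal peaks in the young females, 31.9 and 29.5 in the old females, and 19.9 and 22.1 in the old males. Among peaks with −log10 q of 5 or more the difference was -1.18 per 1000 for old minus young females and 0.413 for old females minus old males. Y-chromosome peaks numbered 2 and 4 in the old males, and 0 in each of the 4 female libraries; Eif2s3y had a peak in old male replicate 1, with −log10 q of 2.65.

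**Figure D4:**
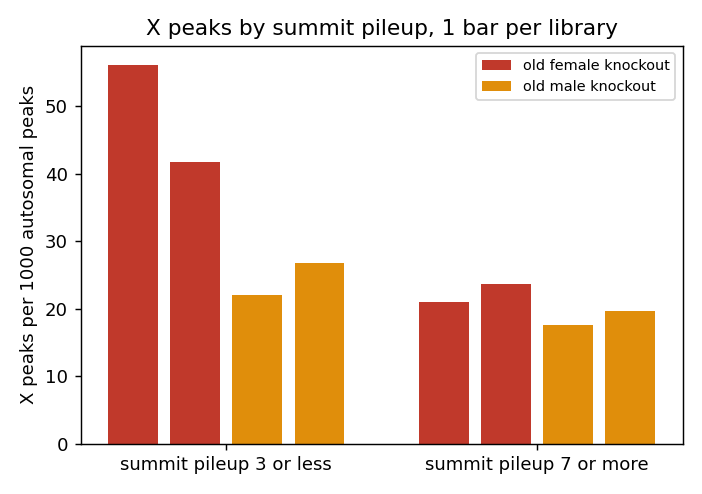
X-chromosome peaks per 1000 autosomal peaks (y axis) in the old female and old male libraries, 1 bar per library, for peaks with a summit of 3 reads or fewer and of 7 reads or more. Among the weak peaks the old females have 56.1 and 41.7 and the old males 22 and 26.8; among the strong peaks the values are 21 and 23.6, and 17.6 and 19.7.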

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

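Matched depth for peak numbers, gene-end shares, X peaks and lists, and the summit rule, were chosen after the data were seen; the cause of each change was not tested unless named. Peak numbers kept their direction in every setting run (all p in the exact tests stayed at the smallest possible), and so did library similarity. At matched depth the log2 differences in peak number were -0.88 for age and -0.63 for sex. At −log10 q of 5 or more the groups lay further apart than in the full lists. Young females then had 27853 and 29319 peaks, old females 2303 and 1729, and old males 3691 and 4683. With the replicate number as a block, log2 differences were -2.56 and -0.81 (exact p = 0.5, the smallest possible), and the replicate numbers are not known to pair mice. None of the lists reached an adjusted p under 0.05 in the 11 settings run for each comparison (lowest 0.061 for age, with the summit rule, and 0.12 for sex, without old male replicate 1, both for X-linked genes with a Y homologue). Counts below give the deeper group first, then old females. With equal list lengths, which keep fewer peaks by construction, age gave 1176 and 129 regions and 907 and 86 genes, and sex 679 and 172 regions and 354 and 126 genes. Matched depth gave 2528 and 73 regions and 1497 and 42 genes for age. A −log10 q of 5 or more left 2 regions only in old females for age, and for sex 919 and 29 regions and 24 genes only in old females. A peak in either library gave 3322 regions and 65 genes only in old females for age, and for sex 10042 and 4321 regions and 2502 and 704 genes. Peaks covering 50% of the region gave 519 and 28 regions for sex. Leaving out a library moved regions only in old females from 7 to 1775 and genes from 0 to 33 for age. For sex, regions only in males ranged from 1841 to 6226 and only in females from 187 to 2435, and genes from 1031 to 1832 and from 136 to 473. The gene-end share, old females minus young, was -18.4 with equal lists, -3.77 at matched depth, 39.8 at −log10 q of 5 or more and 14.5 with 2.5 kb windows; minus old males it was -7.33, 3.11 and 12.8 in the first 3. X peaks per 1000, old females minus young, were 16.4 with equal lists, 10.5 at matched depth and -1.18 at −log10 q of 5 or more, and 0.413 minus old males at that threshold. Of the 36 genes named by rank, 10 lost the difference with the summit rule and 12 with 2.5 kb windows. At −log10 q of 5 or more 4 lost it and at matched depth 1, and 36 kept it with equal list lengths. Motifs were not run. At pileups of 3 or less, 12.7% to 18% of old library peaks overlapped a young female peak, against at least 98.7% at 7 or more, and this limits what counts in the old libraries can show.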

Other observations

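Matched depth was planned for both region counts before the data were examined, but what it was to show there was set down only after the counts were seen. The X chromosome test and the tests of gene-end regions were chosen after the results were seen; those of the pileup ratio, of thinning for the gene-end difference and of calls in the other replicate were set before theirs, the last after the rest were known. The margin asked of that last test was set after its values were seen.

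Regions at gene ends were kept in the old females more often than other regions of the same young or male strength. For age the gene-end share of whole lists, old minus young females, was -3.77 percentage points at matched depth and -18.4 with equal lists. At −log10 q of 5 or more it was 39.8. In the first 2 settings the old female lists still held weak peaks that thinning or ranking cannot add to the young lists. Those 2 values therefore decide nothing about the share at equal depth. Among regions of both young female libraries, 16.5% of 10072 at gene ends and 2.76% of 17754 elsewhere were called in both old females. Within deciles of peak strength the difference was 2.48 percentage points (7.75 within deciles of fold enrichment and 3.6 within deciles of pileup), and in the strongest decile 62.5% against 46%. Starting from regions of both old males, 49.2% of 2844 at gene ends and 24.6% of 1563 elsewhere were kept, a difference of 16.4 points within deciles of strength (16.1 by fold enrichment and 17.6 by pileup). The differences by strength both gave p = 0.0001 in 10000 permutations within deciles, the smallest they can give, over regions and not mice. Thinning for depth alone gave 0.312 points (-0.226 to 1.27 over draws) in the young females and -0.0718 (-1.32 to 1.16) in the old males, but it reuses the reads that set the deciles, so values near 0 are built in and decide nothing. Strength was then taken from 1 library and calls from others at matched depth. The odds ratio for gene ends against other regions within deciles was 1.5 to 1.91 in the old females. In the other young replicate it was 1.18 and 1.03 (at most 1.23 over draws). Call rates were unlike, 34.3% and 26.7% of regions in the other young replicate and 10.1% to 13.3% in the old females. Differences in strength left within deciles can therefore weigh unequally on these odds ratios. For age the higher values in the old females thus do not decide on depth and chance between libraries. From the old males the odds ratio was 2.88 to 3.59 in the old females and 2.64 and 1.99 (at most 2.77) in the other male replicate. That margin is smaller than the difference between those 2 values, so for sex this stays open as well. Age, sex and library quality were not tested against it, and both comparisons rest on the same 2 old female libraries.

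The excess of regions only in young over only in old females stayed at matched depth, 2528 against 73, which argues against depth as the whole cause. In simulated lists of 6000 regions without any loss the same procedure gave 132 against 148. Those lists shared 1 set of positions and differed by counting error alone, so near-equal counts were built in. They check the procedure and add nothing to the case against depth. At the 500 strongest young regions the old female pileup was 1.29 and 1.18 times the depth-scaled young one, so a lower signal common to all regions was not seen there. Scaling by that ratio could not lower the young signal and the count was 2524, which leaves weaker regions undecided. Of the regions only in young over only in old females in the full lists, 1385 had peaks in both old males, which were also old and shallow. At those regions a complete loss in old mice of both sexes was not seen. A weaker signal in old mice of both sexes stays open, since absence here means a peak below the calling threshold. The male libraries were somewhat deeper, with higher pileups at strong regions, so they could pass that threshold where the females did not. Age acting in females alone stays open too. At 17356 regions no old library had a peak. There age, and any difference in how the groups were prepared, stay open as untested, since both deep libraries are young.

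The excess of regions only in old males over only in old females also stayed at matched depth, 1214 against 108. The old female pileup at the 500 strongest male regions was 0.782 and 0.708 times the depth-scaled male one. Thinning the males by the mean ratio as well left 742 (718 to 768) against 183 (166 to 201), so lower signal by a single factor may account for part of the excess and not for all of it. Sex and a quality difference that varies between regions stay open as untested.

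The higher X share in old females sat in weak peaks. Among peaks of pileup 3 or less the odds ratio of X to autosomal peaks, old females over old males, was 2.01 (95% interval 1.53 to 2.64, Fisher's exact p = 2.6e-07 over peaks), and among peaks of 7 or more it was 1.18 (0.92 to 1.51). A candidate explanation is that weak peaks are mostly chance pileups, drawn from 2 X chromosomes in females and 1 in males. Of peaks of pileup 3 or less, 1.67% to 2.91% overlapped a peak of the other replicate, and the 5 Y peaks at that pileup were all in old males.

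Of the 2782 young female regions in the strongest decile, 407 had no peak in either old female library. Of these, 243 had peaks in both old males and 43 in neither.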
